A study of Mus musculus with 8 samples.

How the data were processed

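RNA was sequenced from mouse blastocysts in 3 groups: fresh (2 libraries), vitrified and thawed (3 libraries), and vitrified and thawed in media with 1e-10 M melatonin (3 libraries). The series description names Smart-seq2, a full-length method for small amounts of RNA, while the sample protocol describes bulk RNA, poly(A) selection and a stranded library, so the library method is not settled by the sources. Groups and replicate numbers were taken from the biosample descriptions; the numbers in the sample titles differ from these.

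The authors deposited 1 table of FPKM (fragments scaled by transcript length and by the fragments of the library), computed by the authors per library on genome build mm10 per the labels. The aligner, the counting tool, the gene annotation, any filter and the use of strand are not given in the sources used here. The table held 19688 genes, 0 of them at 0 in every library, and all numeric columns were used. Ensembl identifiers were matched to GENCODE release M21 on GRCm38 (mm10), which gave coordinates and gene types for 19577 genes (99.4%) and left 111 without. Genes were identified by Ensembl identifier, since 17 symbols are duplicated and 22 have the form of dates.

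The number of fragments per library was estimated from the values themselves. For 4978 genes with 1 annotated transcript, FPKM times length fell on whole multiples of 1 step per library for 93.7% to 95.8% of low values (within 0.1 of a whole number, where chance gives 20%). The estimates were between 5815000 and 9996000 fragments, and the sum of FPKM was between 370870.5 and 455879.7. Fragments of the genes in the table made up 97.57% to 99.23% of these estimates. They are thus numbers of fragments assigned to genes and do not give the reads sequenced per library.

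Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), in 1 model of all 8 libraries with a variance trend (eBayes, 4.51 prior degrees of freedom). Genes had to reach 1 FPKM in at least 2 libraries, which 10755 did and 8933 did not. Calls were made at a Benjamini-Hochberg adjusted p below 0.05, two-sided, over all tested genes in each of 3 comparisons: vitrified against fresh, melatonin against vitrified, and melatonin against fresh. Fold changes are differences of mean log2(FPKM + 1) with their SE, and are therefore smaller than ratios of FPKM for genes of low expression. Tables were handled and plotted with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

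Gene lists, 37 pathways and cell type marker sets, were compared with all other tested genes by camera in limma at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested members. The same test with an estimated correlation and the rotation test fry served as alternatives. Where members of a list are correlated by more than the preset value, the p at the preset correlation is too small. The groups, comparisons, tests, gene lists, naming rule and most other settings tried were chosen before the data were examined. Library composition was compared with exact permutation tests of group means, two-sided, which with 10 splits cannot give a p below 0.1. Genes called in both comparisons that share the vitrified libraries were set against 100 simulations of 8 libraries without any effect.

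Genes are named in the text by a fixed rule. Of genes that passed, with a mean of at least 5 FPKM over the groups compared, no overlap between their libraries and a symbol that is not provisional or that of a pseudogene, the 8 highest and 8 lowest fold changes were taken, with remaining places filled by the smallest p in that direction. From each list, up to 2 members per direction with the smallest p were added, along with a set of antioxidant, mitochondrial, lineage, apoptosis and melatonin receptor genes, and up to 8 genes called with opposite signs in the comparisons that share the vitrified libraries.

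Other settings chosen beforehand were limma without the trend, quantile normalization, median ratio scaling, no filter, a mean of at least 5 FPKM, a pseudocount of 0.1, fits of only the groups compared, replicate numbers as a block, each library left out in turn, an adjusted p below 0.1, and a minimum absolute log2 fold change of 1. The model was tested on simulated data in which 200 of 10755 genes were changed, in 5 runs. A change of 1.5-fold was found in 0% of genes, a 2-fold change in 27.4%, 49.0% and 26.3% in the 3 comparisons (vitrified against fresh, melatonin against vitrified, melatonin against fresh), and a 4-fold change in 97.4% or more. The simulated noise was normal, independent between genes and of equal spread in all libraries. The real libraries differ in spread, with estimated weights from 0.5194 (each fresh library) to 3.216 (vitrified replicate 3). These shares can therefore be too high for the real data. The changes were also added on the scale of log2(FPKM + 1), so for genes of low expression they stand for larger changes in FPKM.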

Results

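Gene expression was profiled by RNA sequencing in mouse blastocysts, the stage at which the embryo has formed an outer trophectoderm, an inner cell mass and a fluid-filled cavity. The 8 libraries fell into 3 groups. The control group held 2 libraries of fresh blastocysts, and 3 libraries came from blastocysts that were vitrified, that is, frozen to a glass in cryoprotectant, and thawed. The remaining 3 libraries came from blastocysts vitrified and thawed in media that contained 1e-10 M melatonin, an antioxidant hormone. The labels number the replicates as biosamples and do not state whether these were separate animals, embryo pools or cultures, so all p-values measure the spread between these samples. Sex-linked transcripts, given further below, leave it likely that the libraries came from single embryos or small pools. The deposited table gave FPKM for 19688 genes. An estimated 5815000 (fresh replicate 2) to 9996000 fragments (fresh replicate 1) stood behind each library, so that 1 FPKM of a transcript of 2 kb corresponded to 11.6 to 20.0 fragments.

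Vitrified blastocysts without melatonin had more detected genes than the other groups. Between 15749 and 16400 genes were above 0 FPKM in the 3 vitrified libraries, against 14260 and 14741 in the 2 fresh and 14544 to 14889 in the 3 melatonin libraries. The nuclear noncoding RNA Malat1 reached 145 ± 4.90 FPKM (SD, n = 3) in the vitrified group and 79.9 ± 12.7 (SD, n = 3) with melatonin, and was listed at 11.4 and 93.4 FPKM in fresh replicates 1 and 2. Transcripts of the mitochondrial genome took 11.3% and 6.56% of the summed FPKM in fresh replicates 1 and 2, 5.02 ± 0.753% (SD, n = 3) in the vitrified and 4.52 ± 0.362% (SD, n = 3) in the melatonin group. The difference from fresh gave an exact permutation p of 0.1 in both cases (two-sided), which is the smallest that the 10 splits of 5 libraries allow. The first principal component, with 29.1% of the variance, set fresh replicate 1 apart at -52.5, while fresh replicate 2 lay at -14.2 and the other 6 libraries between 3.29 and 18.4. The second, with 25.2%, placed the vitrified libraries between 6.76 and 34.8 and the melatonin libraries between -26.2 and -14.5, with fresh replicate 1 at 8.08 and fresh replicate 2 at -15.4.

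**Figure D1:**
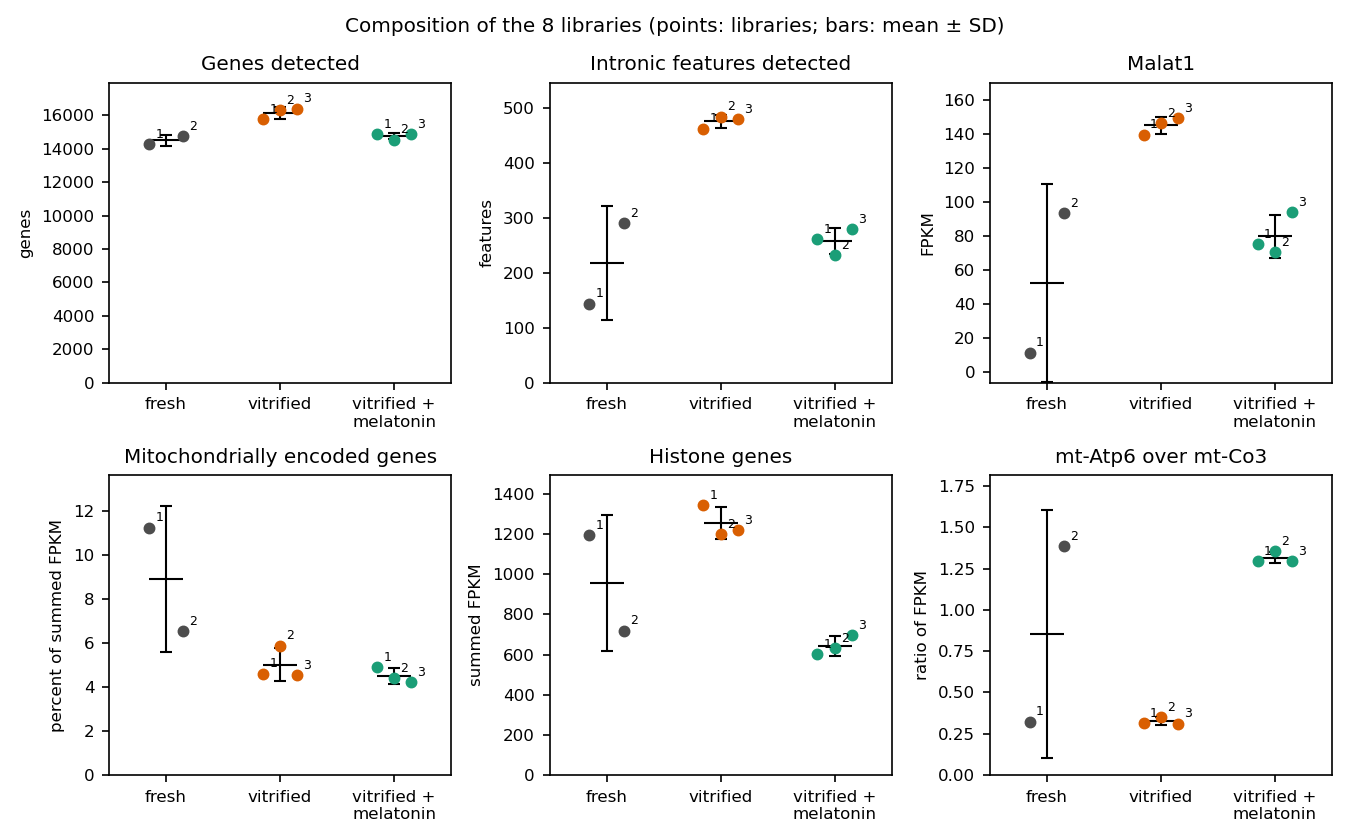
Composition of each library by group: genes above 0 FPKM, intronic features detected, Malat1 in FPKM, mitochondrially encoded transcripts in percent of summed FPKM, summed FPKM of histone genes, and the FPKM ratio of mt-Atp6 to mt-Co3. Points are libraries with their replicate number and bars are the mean ± SD; the vitrified libraries hold 15749 or more detected genes and the other 5 hold 14889 or fewer, while the ratio is 0.353 or lower in fresh replicate 1 and the vitrified libraries and 1.295 or higher in fresh replicate 2 and the melatonin libraries.

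The comparison of vitrified with fresh blastocysts addressed what freezing and thawing change in the transcriptome. Nanog, a transcription factor of pluripotent cells (chromosome 6, 122707489 to 122714633, mm10), rose from 6.65 ± 4.46 FPKM (SD, n = 2) in fresh to 31.2 ± 2.60 (SD, n = 3) in vitrified blastocysts, a log2 fold change of 2.21 ± 0.33 (SE) with a limma adjusted p of 0.0394. Chac1, an enzyme that degrades glutathione and a target of the integrated stress response (chromosome 2, 119351229 to 119354381), fell from 39.8 ± 2.82 FPKM to 4.14 ± 0.787 (log2 fold change -3.00 ± 0.50, adjusted p = 0.0394). Atf4, the transcription factor that drives this response, fell from 149.6 ± 11.4 to 75.1 ± 3.11 FPKM (-0.98 ± 0.18, adjusted p = 0.0477). Cldn4, a tight junction protein of the trophectoderm (chromosome 5, 134945119 to 134946934), fell from 927 ± 73.0 to 400.3 ± 81.3 FPKM (-1.23 ± 0.18, adjusted p = 0.0394). Arpc1b, a subunit of the Arp2/3 complex that branches actin filaments (chromosome 5, 145114215 to 145130705), fell from 51.1 ± 5.28 to 11.6 ± 2.08 FPKM (-2.06 ± 0.21, adjusted p = 0.0178).

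In all, 93 of 10755 genes tested with limma had an adjusted p below 0.05 between vitrified and fresh blastocysts. Of these, 82 were higher and 11 lower after vitrification, and 75 were protein-coding. At an unadjusted p below 0.05 there were 2169 genes (1679 higher, 490 lower), where 538 are due by chance, and 37.0% of tested genes had no overlap between the groups, where chance gives 20%. Other genes that rose were the gap junction protein Gja1 (log2 fold change 2.01 ± 0.36), the SLC4 family transporter Slc4a11 (1.93 ± 0.31), the integrin subunit Itgb5 (1.67 ± 0.30) and Npl, an enzyme of sialic acid breakdown (1.61 ± 0.23). Spp1, which encodes the secreted protein osteopontin (1.61 ± 0.30), Lpcat1, an acyltransferase of phosphatidylcholine synthesis (1.60 ± 0.21), and the lipid carrier Apoe (1.58 ± 0.26) rose as well. Other genes that fell were Reep6, a protein of the endoplasmic reticulum (-2.65 ± 0.32), mt-Atp6, a subunit of ATP synthase encoded in the mitochondrial genome (-1.75 ± 0.21), Psph, which catalyses the last step of serine synthesis (-1.39 ± 0.20), and the adaptor complex subunit Ap4s1 (-0.94 ± 0.17).

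The median of all tested genes lay 0.14 (log2) above fresh, against which single fold changes should be read, and scaling that removed this shift also changed the split: 3 higher and 4 lower with median ratio scaling (all 7 among the 93), and 0 higher and 3 lower with quantile normalization. With trends of GC content and transcript length removed, 20 were higher and 20 lower. Only 1 gene passed with the biosample number as a block. With the title number as a block, fresh replicate 2 stands alone in its block (number 5), so the comparison rests on fresh replicate 1. The median of all tested genes was then 0.211 above fresh. Y-linked transcripts were absent from 2 of the 3 vitrified libraries and from 0 of the other 5. With embryo sex as a covariate, chosen after seeing the data, 4 genes passed, 1 higher and 3 lower, of which 1 was among the 93. With this covariate every comparison with the vitrified group, of genes or lists, rests on vitrified replicate 1, its only library with Y-linked transcripts. With library weights 1 gene passed, as lower. Leaving out single libraries gave 433 genes without fresh replicate 2, 17 without fresh replicate 1, 7, 8 and 2 without vitrified replicates 1, 2 and 3, and 41, 51 and 6 without melatonin replicates 1, 2 and 3. Of the genes named for this comparison, Arpc1b and the noncoding Gm11100 kept their calls in all 8 of these fits, and mt-Atp6 in 5. Calls were kept in 3 of 8 for Nanog, Cldn4, Lpcat1, Reep6, Npl, Psph, Hk2 and Rrm1, and in 2 for Chac1 and Perp. They were kept in 1 of 8 for Atf4, Gja1, Slc4a11, Itgb5, Spp1, Apoe, Mcm7, Ctsb, Ezr, Ptges and Psmb9, and in 0 for Ap4s1 and Hdac2.

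Among the gene lists fixed beforehand, the 13 mitochondrially encoded genes were lower after vitrification as a list (median log2 fold change -0.80, camera adjusted p = 8.76e-08 with the preset correlation, and adjusted p = 0.711 with an estimated correlation). The estimated correlation between members was 0.702 for this list and 0.627 for the cytosolic ribosome. Both lie far above the preset 0.01, so the preset p overstates the evidence for these lists. Only mt-Atp6 passed on its own, against 6 lower adjusted over the list alone. The list also depended on fresh replicate 1, with its larger mitochondrial share: without that library its median was -0.17 and its adjusted p 0.248, and without fresh replicate 2 the median was -1.38. The cytosolic ribosome was lower by the list test (median -0.19, adjusted p = 1.91e-07, and adjusted p = 0.761 with an estimated correlation), with 0 of 76 members past the limma test or adjusted over the list alone, and a median of -0.01 (adjusted p = 0.27) without fresh replicate 1. Its median was -0.36 without fresh replicate 2, and -0.06 and -0.29 without vitrified replicates 1 and 2. It was -0.41 with embryo sex as a covariate and -0.30 with trends of GC content and transcript length removed. The mitochondrial ribosome (median -0.13), respiratory complex I (-0.14) and the nuclear genes of complexes II to IV and ATP synthase (-0.16) passed as lists in the lower direction, with adjusted p of 2.21e-06, 0.00201 and 0.00154. They had adjusted p = 0.711, 0.761 and 0.761 with an estimated correlation, 0 members passed alone, and without fresh replicate 1 the medians were -0.05, -0.08 and 0.01 (adjusted p = 0.0552, 0.27 and 0.603). Without fresh replicate 2 their medians were -0.23, -0.22 and -0.29, without vitrified replicate 1 those of complex I and of complexes II to IV were -0.09 and -0.07, and without vitrified replicate 2 that of the mitochondrial ribosome was -0.20. With GC content and length trends removed the medians were -0.24, -0.22 and -0.27, and with embryo sex as a covariate those of complex I and of complexes II to IV were -0.27 and -0.28. With quantile normalization these latter lists did not pass (medians -0.10 and -0.08, adjusted p = 0.559 and 0.85), and the median of mitochondrially encoded genes was -0.52.

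Genes of the unfolded protein and integrated stress response were lower as a list (median -0.36, adjusted p = 2.33e-06, and adjusted p = 0.711 with an estimated correlation). Of 35 members tested, 2 fell, Chac1 and Atf4, and 33 did not pass; adjusted over the list alone, 10 were lower and 1 higher. The list of p53 targets and DNA damage was higher (median 0.66, adjusted p = 0.000221, and adjusted p = 0.283 with an estimated correlation). Of its 29 members, Perp, a p53 target of cell adhesion, rose from 46.3 ± 3.48 to 138 ± 27.9 FPKM and 28 did not pass, with 10 higher and 1 lower adjusted over the list alone. The DNA repair gene Brca1 was at 3.91 ± 0.791 FPKM against 1.32 ± 0.423 without passing (adjusted p = 0.0576). Cell cycle genes were higher as a list (median 0.50, adjusted p = 0.000652, and adjusted p = 0.711 with an estimated correlation): 2 of 39 rose, the ribonucleotide reductase subunit Rrm1 (1.03 ± 0.16) and the replication helicase subunit Mcm7 (0.87 ± 0.15), and 10 were higher adjusted over the list alone. Epiblast and pluripotency markers were higher (median 0.78, adjusted p = 0.00114, and adjusted p = 0.711 with an estimated correlation), with Nanog as the 1 of 25 members past the test and 12 higher adjusted over the list alone. Tdgf1, a coreceptor of Nodal, was at 58.7 ± 9.41 against 14.2 ± 15.2 FPKM and did not pass (adjusted p = 0.0607). Without fresh replicate 1 the medians of the stress response, cell cycle and epiblast lists were -0.57, 0.27 and 0.47, and without fresh replicate 2 that of the stress response was -0.11. With GC content and length trends removed, the medians of p53 targets and the cell cycle were 0.40 and 0.32.

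The list of DNA methylation and epigenetic regulators was higher (median 0.38, adjusted p = 0.00766), and so was that of fatty acid oxidation and lipid storage (median 0.36, adjusted p = 0.00949), both with adjusted p = 0.711 with an estimated correlation. In the first, the histone deacetylase Hdac2 rose (0.99 ± 0.18) and 28 of 29 did not pass, with 4 higher adjusted over the list alone. In the second, 0 of 25 passed and 2 were higher adjusted over the list alone, among them Plin3 at 103 ± 17.2 against 54.2 ± 0.556 FPKM. Without fresh replicate 1 the median of the first fell to 0.16 (adjusted p = 0.38). The fatty acid list no longer passed without fresh replicate 1 or 2 (adjusted p = 0.0586 and 0.0574), though its medians there, 0.41 and 0.53, were no smaller; the first had a median of 0.575 without fresh replicate 2. With GC content and length trends removed the medians were 0.13 and 0.23. That of DNA methylation was 0.16 with quantile normalization and 0.23 (adjusted p = 0.138) at a mean of at least 5 FPKM. The 4 lists that kept their calls without each library were those of the unfolded protein response, p53 targets, the cell cycle and the epiblast. With embryo sex as a covariate the epiblast list had a median of 0.51 (adjusted p = 0.216) and DNA methylation one of 0.31 (0.0569), a smaller move, while that of fatty acid oxidation was 0.55.

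The other 22 lists did not pass between vitrified and fresh blastocysts, with adjusted p from 0.058 for the cytoskeleton to 0.99 for imprinted genes. Antioxidant enzymes had a median of 0.06 and a mean of 0.14 while the list test pointed lower (adjusted p = 0.755), and 0 of 28 members passed. Superoxide dismutases Sod1 and Sod2 were at 39.9 ± 13.3 and 235 ± 17.7 FPKM after vitrification, against 26.8 ± 5.09 and 231 ± 47.7 in fresh blastocysts. NRF2 targets, the genes of the oxidative stress response, also had a median and mean above 0 (0.12 and 0.07) with a list test pointing lower (adjusted p = 0.726), and 0 of 31 passed. Single members of lists that did not pass as a whole rose: hexokinase Hk2 of glycolysis (1.17 ± 0.17), Ctsb, Itgb5 and Spp1 of implantation and hatching, Ezr of the cytoskeleton, Psmb9 of the proteasome and Ptges of the trophectoderm. Markers of the trophectoderm had a median of -0.03 and a mean of 0.04 (adjusted p = 0.187), with Ptges higher, Cldn4 lower and 29 of 31 not passed. Primitive endoderm markers had a median of 0.16 and a list test pointing lower (adjusted p = 0.813), and 0 of 25 passed. With embryo sex as a covariate they passed as lower (median -0.57, camera adjusted p = 0.0121), but there vitrified replicate 1 alone stands for the vitrified group. Their summed FPKM was 330.3 in that library and 590.2 and 407.4 in vitrified replicates 2 and 3. Without fresh replicate 2, the lists of sterol synthesis, the proteasome, the cytoskeleton and implantation passed (adjusted p = 0.00174, 0.0282, 0.0471 and 0.021), and without vitrified replicate 1 those of the proteasome and the cytoskeleton (0.034 and 0.016). These 2 also passed with library weights (0.0279 and 0.0421), and heat shock and the citrate cycle with quantile normalization (0.0248 and 0.00731).

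Further lists were of mitochondrial biogenesis (median 0.31), autophagy (0.15), heat shock (0.15), apoptosis (0.27), the citrate cycle (0.23), sterol synthesis (0.10, with a list test pointing lower), blastocoel junctions (0.16), interferon response (0.33), hypoxia (0.18), implantation and hatching (0.27), glycolysis (0.18), the proteasome (-0.06), the cytoskeleton (-0.07), imprinted genes (0.18), cumulus cells (0.40) and melatonin synthesis and the clock (0.00). Immediate early genes had a median of -0.20 against a mean of 0.06, and oocyte transcripts a median of 0.00 against a mean of -0.10. Cumulus cell markers summed to 51.9 ± 0.273 FPKM (SD) in fresh, 52.5 ± 4.72 in vitrified and 46.4 ± 12.8 in melatonin libraries. Fibroblast, blood, sperm and early cleavage markers had too few members at 1 FPKM for a list test. Their sums in the 3 groups were 15.3, 25.5 and 24.1 FPKM for fibroblast, 6.23, 11.8 and 8.06 for blood, 4.72, 9.51 and 9.02 for sperm, and 18.9, 31.5 and 25.6 for early cleavage markers.

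**Figure D2:**
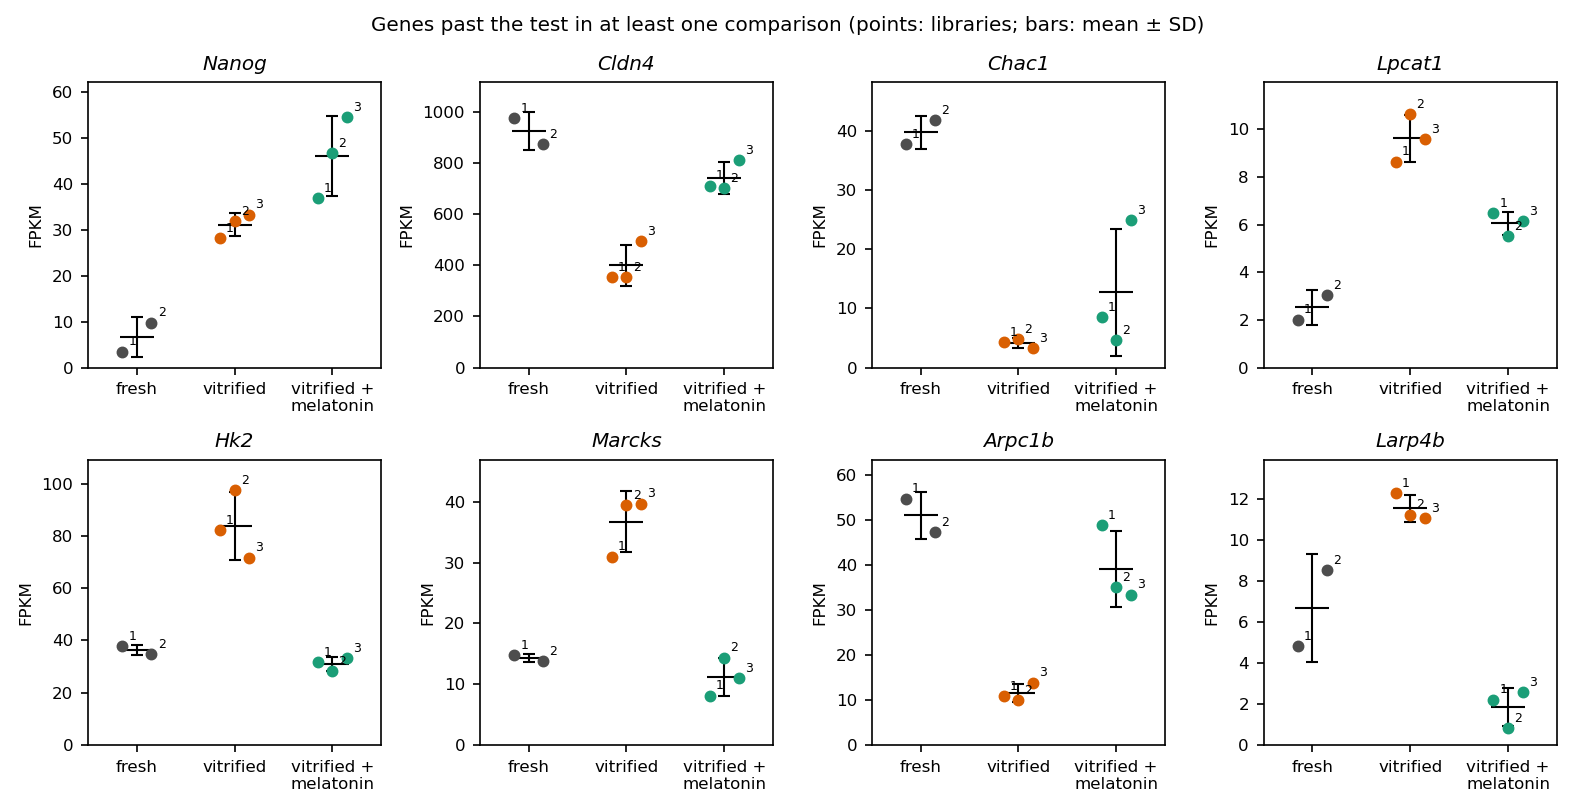
FPKM of 8 genes that passed the limma test in at least 1 comparison, by group (points are libraries with their replicate number, bars the mean ± SD). Nanog averages 6.65 FPKM in fresh, 31.2 in vitrified and 46.1 in melatonin libraries, and Hk2 36.3, 83.8 and 31.0.

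The comparison of vitrification with and without melatonin addressed what the added melatonin changes. Hk2, which catalyses the first step of glycolysis (chromosome 6, 82725025 to 82774454), fell from 83.8 ± 13.0 FPKM (SD, n = 3) without to 31.0 ± 2.60 (SD, n = 3) with melatonin, a log2 fold change of -1.40 ± 0.15 (SE) with a limma adjusted p of 0.0172. Marcks, an actin-binding substrate of protein kinase C, fell from 36.7 ± 4.99 to 11.2 ± 3.13 FPKM (-1.65 ± 0.21, adjusted p = 0.0246), and the RNA-binding protein Larp4b from 11.5 ± 0.662 to 1.87 ± 0.927 FPKM (-2.18 ± 0.29, adjusted p = 0.0246). Arpc1b rose from 11.6 ± 2.08 to 39.2 ± 8.49 FPKM (1.67 ± 0.19, adjusted p = 0.0172) and mt-Atp6 from 1476 ± 307 to 3858 ± 244 FPKM (1.40 ± 0.19, adjusted p = 0.028).

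With melatonin, 15 of 10755 genes passed, 3 higher and 12 lower, and 8 of them were protein-coding. Only 1 gene passed with the biosample number as a block, and 0 with the title number, where vitrified replicate 2 and melatonin replicate 1 stand alone in their blocks. The group without melatonin held the 2 libraries that lack Y-linked transcripts. With embryo sex as a covariate, chosen after seeing the data, 3 genes passed as higher and 0 as lower, and 1 of these was among the 15; with library weights, 36 were higher and 197 lower, with all 15 among them. At an unadjusted p below 0.05 there were 1596 genes (494 higher, 1102 lower), and 24.7% of genes did not overlap between the groups, where chance gives 10%. The linker histones Hist1h1b (-1.86 ± 0.27) and Hist1h1e (-1.73 ± 0.25) and the immediate early transcription factor Jun (-1.61, 0.328 ± 0.157 against 3.08 ± 0.72 FPKM) fell. So did the noncoding Yam1 (-2.59 ± 0.30), which lies on the opposite strand of the noncoding Gm42418 (chromosome 17, 39846958 to 39848788), itself at -2.62 and picked out after its values were seen. Values of such overlapping pairs and of histone genes, which have close copies, are uncertain, since the sources do not state how reads were assigned or whether strand was used. Cldn4 was at 743 ± 61.8 FPKM with and 400.3 ± 81.3 without melatonin and did not pass (0.91 ± 0.16, adjusted p = 0.0802). Other genes short of the threshold were Actg2, a smooth muscle actin (2.92 ± 0.58), the chromatin-associated Sltm (0.85 ± 0.16), Rpe of the pentose phosphate pathway (0.77 ± 0.15), Pstpip2 (0.80 ± 0.16), Gpcpd1 (0.74 ± 0.16), Ptov1 (-1.65 ± 0.26) and the sulfatase Sulf2 (-1.12 ± 0.18), with adjusted p from 0.0695 to 0.109. Without single libraries, 67 and 68 genes passed without fresh replicates 1 and 2, 15, 8 and 5 without vitrified replicates 1, 2 and 3, and 2, 11 and 1 without melatonin replicates 1, 2 and 3. Of the genes named here, Gm11100 kept its call in 8 of these 8 fits, Hk2 in 6, Arpc1b and Yam1 in 5, Marcks in 4, Larp4b, mt-Atp6 and Hist1h1b in 3, and Hist1h1e and Jun in 2.

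Cytosolic ribosome genes were lower with melatonin as a list (median -0.37, camera adjusted p = 3.34e-09, and adjusted p = 0.831 with an estimated correlation). Of 76 members, 0 passed, also adjusted over the list alone. Rpl10, for instance, was at 5.20 ± 0.377 FPKM against 10.7 ± 3.48 (limma adjusted p = 0.17). Its level is low for this list, which summed to 10320 ± 1256 FPKM (SD) with and 12810 ± 1509 without melatonin. Primitive endoderm markers were lower (median -0.53, adjusted p = 0.00194, and adjusted p = 0.831 with an estimated correlation), with 0 of 25 past the test and 1 lower adjusted over the list alone, among them Dkk1, an inhibitor of Wnt signalling, at 14.6 ± 3.57 against 36.4 ± 6.50 FPKM. Targets of p53 (median -0.32, adjusted p = 0.0244) and glycolysis (median -0.42, adjusted p = 0.0488) were lower as lists, both with adjusted p = 0.831 with an estimated correlation. Of the p53 list 0 of 29 passed, also adjusted over the list alone; of glycolysis Hk2 fell, 18 of 19 did not pass, and 6 were lower adjusted over the list alone. The unfolded protein response (median 0.20, adjusted p = 0.0244) and mitophagy and autophagy (median 0.07, adjusted p = 0.0488) were higher as lists, both with adjusted p = 0.831 with an estimated correlation. Of their members, 0 of 35 and 0 of 31 passed, also adjusted over the list alone.

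Of the lists called here, the ribosome list alone kept its call without each library. With embryo sex as a covariate, where the vitrified side rests on vitrified replicate 1 alone, only the unfolded protein response kept its call. The medians were then -0.17 for the ribosome (adjusted p = 0.135), -0.11 for primitive endoderm markers (0.847), -0.22 for p53 targets (0.135), -0.23 for glycolysis (0.523) and 0.03 for mitophagy (0.847). With GC content and length trends removed the ribosome median was -0.19, and the unfolded protein response and mitophagy no longer passed at medians of 0.23 and 0.15 (both 0.0547). At a mean of at least 5 FPKM glycolysis shrank to -0.23 (0.063), and calls ended without a change in median for mitophagy (0.147), the unfolded protein response (0.063) and p53 targets (0.0525). With library weights mitophagy, the unfolded protein response and p53 targets ended at 0.09, 0.17 and -0.23 (0.0744, 0.0726 and 0.0667). Mitophagy ended with quantile normalization at 0.13 (0.0923), and with the biosample number as a block both it and glycolysis ended at the same medians (0.0623). Without vitrified replicate 2 the medians of primitive endoderm markers and glycolysis shrank to -0.29 and -0.21 and no longer passed (adjusted p = 0.0842 and 0.0715), while p53 targets (-0.27, adjusted p = 0.0842) and mitophagy (0.06, 0.412) lost their calls with medians nearer to those above. The unfolded protein response shrank to 0.11 without melatonin replicate 1 (0.233) and 0.10 without vitrified replicate 1 (0.0796), and was 0.30 without melatonin replicate 2. Calls of p53 targets and glycolysis ended without melatonin replicate 2 at medians of -0.30 and -0.32 (0.0982 and 0.138). Mitophagy ended without melatonin replicates 1 and 3 at medians no smaller, 0.08 and 0.09 (0.0709 and 0.0827). Glycolysis also ended without melatonin replicate 3 (-0.27, 0.0503), vitrified replicate 3 (-0.34, 0.078) or either fresh replicate, where its median of -0.42 is the same by construction (0.0695). The median of primitive endoderm markers was -0.80 without vitrified replicate 1, and that of mitophagy 0.11 without that library and 0.13 without melatonin replicate 2.

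The other 27 lists did not pass between melatonin and vitrified libraries. Antioxidant enzymes had a median of -0.19 (adjusted p = 0.368) and NRF2 targets one of -0.16 (adjusted p = 0.465), with 0 of 28 and 0 of 31 members past the test. Among them Sod1 was at 23.9 ± 1.31 FPKM with and 39.9 ± 13.3 without melatonin, Cat at 24.0 ± 6.08 and 22.1 ± 4.86, and Gpx4 at 50.9 ± 2.33 and 58.8 ± 2.61. Of mitochondrially encoded genes mt-Atp6 rose and 12 of 13 did not pass (median -0.43, adjusted p = 0.119), and the list passed without either fresh replicate (0.00816). Jun was the 1 of 20 immediate early genes that fell (list median -0.24, adjusted p = 0.0731). Of the cytoskeleton list, Arpc1b rose and 32 of 33 did not pass; its list test pointed higher, with a median of -0.21 and a mean of -0.03. The list test also pointed higher, against medians of -0.02, -0.01, -0.01 and -0.01, for fatty acid oxidation, the mitochondrial ribosome, heat shock and the proteasome, and the citrate cycle had a median of 0.02 against a mean of -0.03. Epiblast markers had a median of -0.36 (adjusted p = 0.349), with Nanog at 46.1 ± 8.80 with and 31.2 ± 2.60 FPKM without melatonin. Trophectoderm markers had a median of 0.12 (adjusted p = 0.131) and clock genes one of 0.43 (adjusted p = 0.0731). Ppargc1a, a regulator of mitochondrial biogenesis, and the apoptosis inhibitor Bcl2 were listed at 0.12 FPKM or less in every library, and the melatonin receptors Mtnr1a and Mtnr1b were not in the table. Other lists passed without vitrified replicate 1 (complexes II to IV, imprinted and immediate early genes, adjusted p = 0.0427, 0.0301 and 0.0314), melatonin replicate 2 (trophectoderm markers, 0.0214) or melatonin replicate 3 (complex I, complexes II to IV, sterol synthesis and the clock, 0.016, 0.0125, 0.0125 and 0.0323). With quantile normalization mitochondrially encoded genes, complexes II to IV, immediate early genes and the clock passed (0.0112, 0.0276, 0.0496 and 0.0405), and immediate early genes with GC content and length trends removed (0.0279).

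The comparison of melatonin-treated vitrified with fresh blastocysts addressed what remains different after vitrification with melatonin. Nanog averaged 46.1 ± 8.80 FPKM (SD, n = 3) in the melatonin group and 6.65 ± 4.46 (SD, n = 2) in fresh blastocysts, without passing (log2 fold change 2.74 ± 0.33 SE, limma adjusted p = 0.112). This fold change is larger, at the same SE, than the 2.21 ± 0.33 called between vitrified and fresh. The call is absent here only through the adjustment over all genes. The mitotic kinesin Kif20a was at 110.0 ± 20.0 against 46.8 ± 10.4 FPKM and the mitotic kinase Plk1 at 68.2 ± 6.16 against 30.2 ± 8.28, and neither passed (adjusted p = 0.116). Mitochondrially encoded mt-Nd4 and mt-Nd5, subunits of complex I, were at 458 ± 36.0 and 353 ± 27.6 FPKM against 1116 ± 415 and 747 ± 225 (adjusted p = 0.116). Cebpb, a transcription factor of the stress response, was at 13.0 ± 3.79 against 54.6 ± 22.7 FPKM.

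No gene passed in this comparison (0 of 10755 with limma, smallest adjusted p 0.112), also with voom weights, while 5 passed with a pseudocount of 0.1. With only the groups compared 2 passed. With the title number as a block the comparison rests on fresh replicate 1 alone, and the median of all tested genes was 0.165 above fresh. At an unadjusted p below 0.05 there were 1985 genes (1252 higher, 733 lower) against 538 due by chance, and 34.3% of genes did not overlap, where chance gives 20%. Vitrified against fresh had 2169 genes at that p. The counts of 93 and 0 calls therefore do not show that melatonin libraries differ less from fresh. Without fresh replicate 2, 565 genes passed (415 higher, 150 lower); 1 passed without fresh replicate 1 or vitrified replicate 2, and 2 without melatonin replicate 1 or 3. Further genes with small p were, on the higher side, Ccdc160 (1.34), the transcription factor Spic (2.53), the cyclin Ccnf (1.06), Pgm1 (1.18) and the tyrosine aminotransferase Tat (2.91). On the lower side they were the carbonic anhydrase Car2 (-3.01), Yaf2 (-1.36), Tmem147 (-0.94), Mettl9 (-0.91) and the nucleosome-binding Hmgn1 (-0.70).

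As a list, cytosolic ribosome genes had a median of -0.58. The camera adjusted p was 8.37e-26 with the preset correlation and 0.499 with the estimated correlation of 0.627, where the list did not pass. Adjusted over the list alone, 42 of 76 were lower, for instance Rps16 at 219 ± 33.2 against 354 ± 22.1 FPKM. Mitochondrially encoded genes were lower (median -1.12, adjusted p = 4.92e-12, and adjusted p = 0.499 with an estimated correlation), with 12 of 13 lower adjusted over the list alone. Their median was -0.56 without fresh replicate 1, which has the larger mitochondrial share, and -1.62 without fresh replicate 2. Complex I (median -0.28), complexes II to IV and ATP synthase (-0.29) and the mitochondrial ribosome (-0.16) were lower with adjusted p of 4.40e-06, 1.50e-06 and 1.50e-06. They had adjusted p = 0.499 with an estimated correlation, and 0 members passed adjusted over the list alone. Immediate early genes (median -0.53, adjusted p = 0.000897, 6 lower adjusted over the list alone), primitive endoderm markers (median -0.43, adjusted p = 0.00194, 3 lower and 1 higher) and the unfolded protein response (median -0.17, adjusted p = 0.0097, 2 lower) were also lower, each with adjusted p = 0.499 with an estimated correlation. Higher were the cell cycle list (median 0.42, adjusted p = 0.000897, 16 higher and 1 lower adjusted over the list alone), fatty acid oxidation and lipid storage (0.43, adjusted p = 0.00161, 3 higher), mitophagy and autophagy (0.34, adjusted p = 0.0185, 3 higher) and epiblast markers (0.55, adjusted p = 0.0224, 2 higher). These too had adjusted p = 0.499 with an estimated correlation, and 0 members of any list passed over all genes. Without fresh replicate 1, mitophagy and epiblast markers shrank to medians of 0.145 and 0.24 and no longer passed (adjusted p = 0.0742 and 0.0874), and without fresh replicate 2, primitive endoderm markers (median 0.00, adjusted p = 0.606) and the unfolded protein response (median 0.06, adjusted p = 0.419) did not. The unfolded protein response also ended without melatonin replicate 2 (median -0.02, adjusted p = 0.136), and mitophagy without melatonin replicate 3 at a median of 0.29 (0.0572).

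Medians of the lists called between melatonin and fresh libraries also moved. Without fresh replicate 1 they were -1.05 for primitive endoderm markers, -0.40 for the unfolded protein response, 0.24 for the cell cycle and -0.17 for complexes II to IV. Without fresh replicate 2 they were -0.28 for immediate early genes, -0.28 for the mitochondrial ribosome and 0.91 for epiblast markers. Without melatonin replicate 1 they were -0.19 for primitive endoderm markers, -0.29 for the unfolded protein response, -0.19 for complexes II to IV and -0.09 for the mitochondrial ribosome. Without melatonin replicate 2 they were -0.22 for primitive endoderm and 0.35 for epiblast markers, and without melatonin replicate 3 -0.255 for the mitochondrial ribosome. With GC content and length trends removed they were -0.18 for complex I and 0.13 for mitophagy, and with quantile normalization -0.14 for complexes II to IV. At a mean of at least 5 FPKM epiblast markers had a median of 0.17 and did not pass (adjusted p = 0.199), and immediate early genes and primitive endoderm markers lost their calls at medians of -0.50 and -0.455 (0.101 and 0.0512). The unfolded protein response ended with quantile normalization (median -0.149, adjusted p = 0.152), and mitophagy with the biosample number as a block (median 0.30, 0.057).

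The other 21 lists did not pass between melatonin and fresh libraries. Antioxidant enzymes had a median of -0.09 (adjusted p = 0.154), with Cat at 24.0 ± 6.08 against 15.2 ± 1.06 FPKM, and p53 targets one of 0.34 (adjusted p = 0.063). NRF2 targets had a median of 0.04 against a mean of -0.07 (adjusted p = 0.205). For apoptosis, interferon response, hypoxia and trophectoderm markers, with medians of 0.04, 0.06, 0.00 and 0.02, the list test pointed lower. Among imprinted genes (median -0.20, adjusted p = 0.154), H19 was at 1.85 ± 0.548 against 13.9 ± 10.3 FPKM and Phlda2 at 1.65 ± 1.21 against 9.58 ± 2.52. Lists that passed without a single library were p53 targets and sterol synthesis (fresh replicate 1, adjusted p = 0.00178 and 0.00194), and antioxidant enzymes, glycolysis, sterol synthesis, DNA methylation and blastocoel junctions (fresh replicate 2, 0.045, 0.0344, 0.0386, 0.037 and 0.0371). Glycolysis and the cytoskeleton passed without melatonin replicate 1 (both 0.0212), and p53 targets and the proteasome without melatonin replicate 2 (0.025 and 0.0343). With quantile normalization heat shock, p53 targets, the citrate cycle and blastocoel junctions passed (0.0111, 0.0452, 0.0039 and 0.00916), with library weights p53 targets (0.0377), and with GC content and length trends removed glycolysis (0.0457).

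**Figure D3:**
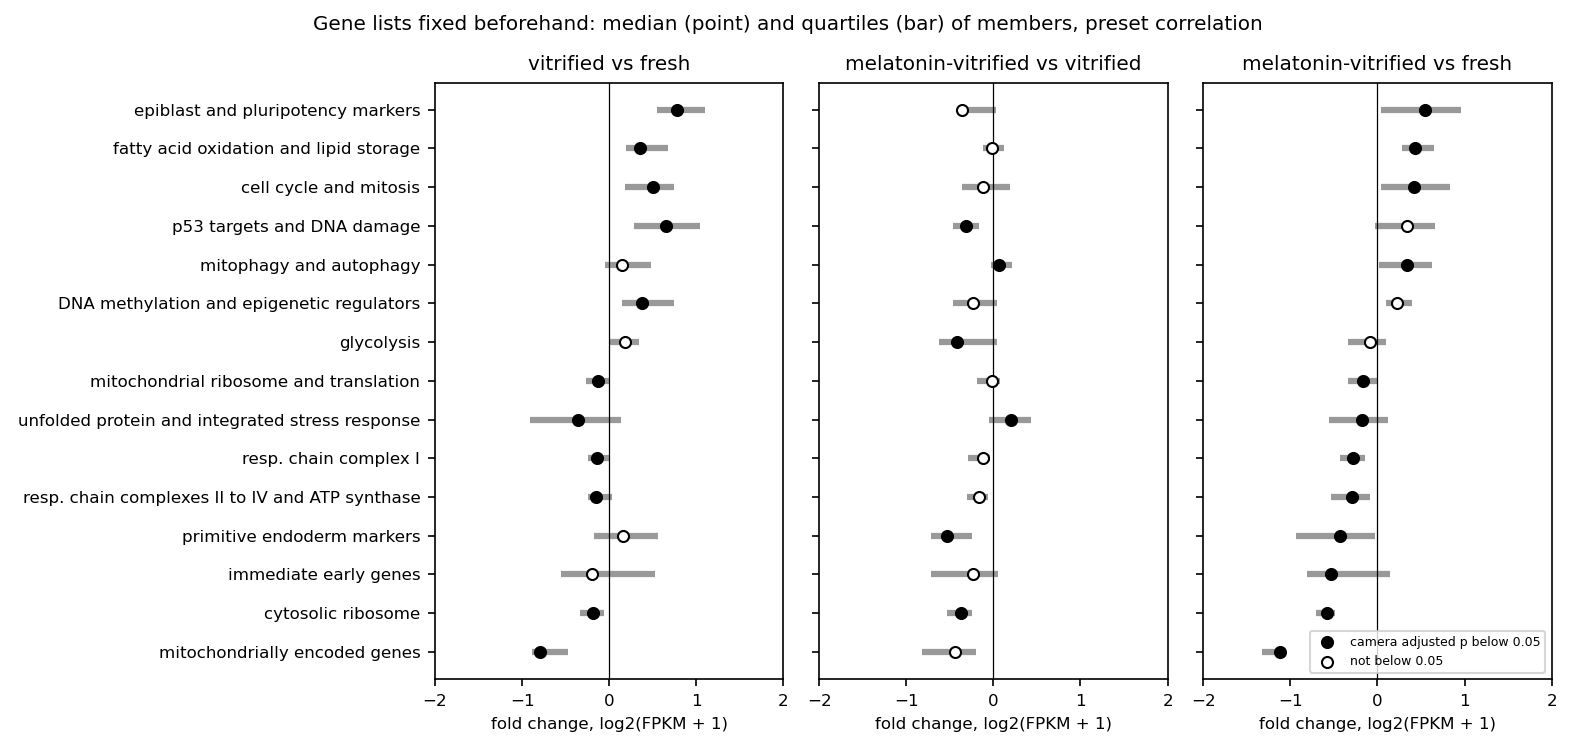
Median (point) and quartiles (bar) of the fold change of each list's tested members, on the scale of log2(FPKM + 1), for lists with a camera adjusted p below 0.05 (filled points) in at least 1 of the 3 comparisons. The adjusted p are those with the preset correlation, and 0 lists passed with an estimated correlation. The cytosolic ribosome lies at -0.19, -0.37 and -0.58, and the mitochondrially encoded genes at -0.80, -0.43 and -1.12.

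Whether melatonin moved back what vitrification had changed was examined with the genes called in both comparisons. Hk2 and Marcks rose with vitrification (1.17 ± 0.17 and 1.29) and fell with melatonin (-1.40 ± 0.15 and -1.65 ± 0.21), while Arpc1b and mt-Atp6 fell (-2.06 ± 0.21 and -1.75 ± 0.21) and rose (1.67 ± 0.19 and 1.40 ± 0.19). Relative to its neighbour mt-Co3, however, mt-Atp6 was at 0.323 in fresh replicate 1, within the vitrified range of 0.311 to 0.353. By this ratio it was lower after vitrification only against fresh replicate 2 (1.39), so a return to the fresh state is not established for mt-Atp6. The noncoding Gm11100 (chromosome 14, 13918444 to 13949558, antisense to the mRNA export gene Thoc7) was at 13.5 ± 2.14 FPKM in fresh (SD, n = 2), 0.1 ± 0.0319 in vitrified (SD, n = 3) and 12.6 ± 1.84 in melatonin libraries (SD, n = 3). Its log2 fold changes were -3.71 ± 0.21 and 3.62 ± 0.18, with adjusted p of 0.000124 and 5.53e-05. The noncoding Gm43628, Gm26518 and Gm28791 and the pseudogene Vmn2r-ps20 were at 4.51 ± 1.66, 1.79 ± 0.346, 1.93 ± 0.266 and 3.12 ± 0.934 FPKM in vitrified libraries and at means of 0.29 or less in the other groups, with Gm26518 listed at 0 in all melatonin and Vmn2r-ps20 in all fresh libraries. With each library left out in turn, calls between vitrified and fresh were kept in 3 of 8 fits for Gm43628, Gm28791 and Vmn2r-ps20. For Gm26518 they were kept in 1 of 8. Calls between melatonin and vitrified were kept in 3 of 8 for Gm43628 and in 2 for Gm26518, Gm28791 and Vmn2r-ps20. Of the 9 genes, 7 overlap another annotated gene, and their values are uncertain where strand was not used in counting. These 9 genes, 6 higher and 3 lower after vitrification, moved in opposite directions, and 0 genes passed in both comparisons in the same direction.

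Since both comparisons use the same 3 vitrified libraries, chance alone makes fold changes run in opposite directions. In 100 simulations 0 genes were called in both comparisons on average and at most, but these hold no effect in either comparison and so give no estimate of the count where vitrified libraries do differ. Independent lists of the sizes found would share 0.0915 genes higher then lower and 0.00307 lower then higher. The 3 vitrified libraries cannot be divided into independent groups with replicates on each side, so part of the excess may come from these shared libraries. Of the 93 genes changed by vitrification, 94.6% had the opposite sign with melatonin, against 88.8% among as many top genes in the simulations. Across all tested genes, which are not independent replicates, the covariance of the fold changes was -0.0987 against a simulated -0.0343, a difference of -0.0644 beside a jackknife SE of 0.0483 over libraries, so that opposition beyond the shared libraries was not established. Pearson's r was -0.48 against -0.45. Among the 82 genes higher after vitrification, the median change with melatonin was -0.61, and their median difference between melatonin and fresh libraries was 0.71. Among the 11 lower genes these medians were 0.91 and -0.53. Selection of the genes in the same vitrified and fresh libraries favours these signs, and no simulated medians were made to set beside them. The fold changes of vitrified and of melatonin libraries against the same fresh libraries had a covariance of 0.146, where 0.0519 was simulated. The simulations gave all libraries the same spread, while the fresh libraries had the lowest estimated weights (0.5194 each). The simulated value can therefore be too low, and a change shared by both vitrified groups is not established by this gap. With embryo sex as a covariate 2 genes had opposite calls, and of the 9 only Gm11100 kept both. The fold changes of the 9 were then 0.822 to 1.078 times those above, while their SE were 1.31 to 1.55 times as large because the effect rests on vitrified replicate 1 alone, so the other calls ended through the wider spread. The 9 genes were selected in fits that favour agreement between the vitrified libraries, so the similar fold changes do not bear on embryo sex. The covariance with the embryo sex covariate was -0.149 against a simulated -0.103. The count of 9 was between 1 and 24 without single libraries: 24 without fresh replicate 2, 4 and 2 without vitrified replicates 2 and 3, and 1 without melatonin replicate 1 or 3.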

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

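The voom weights, library weights, embryo sex covariate, autosomal protein-coding set, removal of GC content and length trends, and fry were chosen after seeing the data; the other settings were planned. Among called results for named genes, 379 of 945 values under alternatives stayed past the threshold, 566 did not, and 0 changed direction; among those not called, 141 of 9107 passed.

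Genes changed between vitrified and fresh (93) numbered 686 at an adjusted p below 0.1, 177 among autosomal protein-coding genes, 40 with GC content and length trends removed, 11 with only the groups compared, 7 with median ratio scaling, 4 with embryo sex as a covariate, 3 with quantile normalization, 1 with no filter and 1 with library weights. Without single libraries they numbered 2 to 433. Between melatonin and vitrified (15) there were 233 with library weights, 68 with only the groups compared, 45 at an adjusted p below 0.1, 8 with quantile normalization, 8 with voom weights, 6 with a pseudocount of 0.1, 6 among autosomal protein-coding genes and 3 with embryo sex, and 1 to 68 without single libraries. Between melatonin and fresh (0) there were 5 with a pseudocount of 0.1, 2 with only the groups compared and 0 to 565 without single libraries.

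Genes moved in opposite directions (9) numbered 32 at an adjusted p below 0.1, 5 with voom weights, 4 with median ratio scaling, a pseudocount of 0.1 or GC content and length trends removed, 3 among autosomal protein-coding genes, 2 with quantile normalization, only the groups compared or embryo sex, 1 with no filter or library weights, and 1 to 24 without single libraries. The covariance of the effects (-0.0987) was -0.149 with embryo sex, -0.243 with a pseudocount of 0.1 and -0.298 with voom weights.

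Gene lists called between vitrified and fresh (11) numbered 0 with an estimated correlation, 3 with fry, and 4 to 14 without single libraries. Between melatonin and vitrified (6) they numbered 0 with an estimated correlation, 0 with fry, 2 at a mean of at least 5 FPKM, 3 with library weights, 1 with embryo sex, and 2 to 8 without single libraries. Between melatonin and fresh (12) they numbered 0 with an estimated correlation, 0 with fry and 11 to 15 without single libraries. Filters, gene classes and thresholds change which genes are tested or called by construction; for the other settings the cause was not tested. A fresh library left alone was assumed to vary like the other groups. The test fry asks whether a list moved at all, while camera compares it with the other genes. Its 3 lists between vitrified and fresh were p53 targets (fry adjusted p = 0.00632), fatty acid oxidation and apoptosis (both 0.0232). Apoptosis was not among the 11 lists called by camera.

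With the biosample number as a block, the counts were 1 (vitrified against fresh), 1 (melatonin against vitrified) and 1 (opposite directions). With the title number as a block they were 39, 0 and 0, and 44 between melatonin and fresh. The lists called with the biosample number as a block numbered 11, 4 and 11 in the 3 comparisons. The same biosample number gave correlations of 0.121, 0.0684 and -0.0305 between vitrified and melatonin deviations from the group mean. Correlations so few and small cannot decide whether the numbers pair the samples. Vitrified replicates 1 and 2 correlated best with the melatonin library of their own number, and replicate 3 did not.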

Other observations

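The tests for a handling step shared by the vitrified libraries, a library batch of fresh replicate 1, overlapping genes and female embryos were chosen only after the result was seen, and the histone, mt-Atp6 and embryo sex values were looked up after other results. Transcripts of the Y chromosome set apart 2 of the 8 libraries. Eif2s3y, a Y-linked gene of translation initiation, was listed at 0 in vitrified replicates 2 and 3 and at 14.8 to 24.6 FPKM in the other 6 libraries. Xist, the RNA that silences an X chromosome in female cells, was at 10.45 and 8.14 FPKM in vitrified replicates 2 and 3 and below 1 FPKM in the other 6. Of the 93 genes changed between vitrified and fresh blastocysts, 1 lay on the X chromosome, which held 362 of the tested genes.

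Replication-dependent histone genes, 71 in the table, whose transcripts mostly lack a poly(A) tail, summed to 1256 ± 79.5 FPKM (SD, n = 3) in vitrified and 644 ± 49.3 (SD, n = 3) in melatonin libraries, and to 1197 and 719 in fresh replicates 1 and 2. The ratio of mt-Atp6 to mt-Co3, neighbours in the mitochondrial genome, was 0.312, 0.353 and 0.311 in vitrified, 1.295, 1.36 and 1.297 in melatonin libraries, and 0.323 and 1.39 in fresh replicates 1 and 2. Gm42418 and Yam1 together reached 145 to 250.3 FPKM in vitrified, 22.8 to 34.3 in melatonin libraries, and 78.3 and 39.1 in fresh replicates 1 and 2. Neat1, a nuclear noncoding RNA, was at 2.31 ± 0.490 FPKM in vitrified, 1.28 ± 0.0584 in melatonin libraries, and 0.145 and 1.75 in fresh replicates 1 and 2.

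Vitrified libraries held more detected genes and more intronic features, with 463 to 485 of 719 such features above 0 against 144 to 291 in the other 5 libraries. The number of fragments assigned to genes is argued against as the source. After thinning to the same number of these, the lowest vitrified library still lay 448.9 single-transcript genes above the highest other. Intronic features in host genes at 10 FPKM or more differed more between vitrified and other libraries (median log2 difference 0.787 over 110 features) than those in hosts below 1 FPKM (0.559 over 311). The gap of 0.2284 (permutation p = 0.0185) points away from genomic DNA as the whole source. The permutation shuffled features, which are not independent replicates, so its p does not measure the spread between libraries and excludes nothing. Features in silent hosts were higher in vitrified libraries as well, in 77.5%, so genomic DNA could still account for a part. A batch or handling step shared by the 3 vitrified libraries, the lowest of which had 1.591 times the intronic features of the highest other, and an effect of vitrification that melatonin limits cannot be told apart, since the labels name no batch.

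Fresh replicate 1 lay with the vitrified and fresh replicate 2 with the melatonin libraries in the mt-Atp6 ratio and the histone sum, but in genes detected, intronic features, Malat1 and Neat1 fresh replicate 1 was the library furthest from the vitrified group. Its Spearman correlations over genes were no higher with vitrified (0.918 to 0.925) than with melatonin libraries (0.918 to 0.926). Those of fresh replicate 2 were higher with each melatonin library (0.9394 to 0.949) than with any vitrified library (0.9281 to 0.933). Across 4113 genes, which are not independent replicates, the difference between the fresh libraries correlated with that of vitrified minus melatonin libraries at r = 0.3537, while the highest absolute r among the other 9 of 10 splits was 0.355. Removing trends with GC content and transcript length left 84.4% of r, between the bounds set for this test, so a trend of this kind could account for a small part. A library batch shared by fresh replicate 1 and the vitrified libraries cannot be told apart from the spread of fresh blastocysts, since another split followed the fresh difference as closely and the labels name no batch; no biological explanation was tested.

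The 9 genes that moved in opposite directions with vitrification and melatonin include several that overlap other genes. Of the 9, 7 overlap another annotated gene against 54.9% of other tested genes, an odds ratio of 2.876 (exact p = 0.198, two-sided), so reads divided between overlapping genes cannot be told apart from a change in expression with so few genes. Female embryos in the vitrified group stay open: vitrified replicate 1, which has Y-linked transcripts, lay outside the other 5 libraries for 100% of these genes, but it is 1 library and the genes were selected for that separation. With embryo sex as a covariate 1 of the 9 kept both calls; fold changes stayed at 0.822 to 1.078 times their size while SE grew 1.31 to 1.55 times, so the ended calls are no evidence that embryo sex caused the change. Nor are the similar fold changes evidence against embryo sex, since selection of the genes favoured agreement between vitrified replicate 1 and the rest of its group. An effect of melatonin on vitrified embryos stays open as a hypothesis, as does a batch shared by the vitrified libraries. For the 15 genes called between melatonin and vitrified libraries, 10 splits of 6 libraries cannot give a share below 0.1; the real split gave 15 genes, as many as 1 of 10 splits including itself, and the highest of the others gave 1.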
